A study of Gallus gallus with 3 samples.

How the data were processed

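Single-cell RNA sequencing of dissociated whole chicken limbs was analysed at the Hamburger-Hamilton stages HH21, HH24 and HH27, with 1 library per stage. Cells were dissociated with trypsin and captured on the 10x platform with v2 chemistry, per the labels' protocols. The libraries were processed with Cell Ranger 3, per the submitters' processing notes; the genome build and the annotation are not given in the sources used here. The HH21 and HH24 libraries were each sequenced in 2 runs, per the series design text, so run and stage differ together for HH27. The series title names hind limbs, whereas the sample labels and the design text name forelimbs. Genes that tell these limbs apart could not be found by name, so the tissue is called limb throughout.

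The deposited tables held, per cell, raw UMI counts for 16828 Ensembl gene identifiers, which the authors had not normalized. The counts of each cell summed to the UMI total the authors gave in all 10531 cells. The authors also deposited, per the file headers, the percent of UMIs in mitochondrial genes, and 13 gene columns accounted for that percentage in every cell. The deposited S and G2M scores ran from 0 to 1 per cell, and the method behind these scores is not given in the sources used here. Cluster numbers and population names were taken from the authors' deposited annotation, with their question marks and abbreviations kept as written. The reference table of gene symbols matched 0 of the 16828 identifiers, so the tables used here do not pair identifiers with names. The rule for named genes, which took a set number of the largest and smallest log2 ratios among genes with a symbol, therefore could not be applied. In its place, the 2 identifiers with the largest and the 2 with the smallest log2 ratio in mesenchyme between HH27 and HH21 are given, a choice made after their values were seen. The marker lists and pathway lists fixed in advance could not be read either, apart from the mitochondrially encoded genes.

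All deposited barcodes were kept. Depth differed between libraries: HH21 held 2990 cells with 8244919 UMIs (median 2365 per cell), HH24 held 5352 cells with 10839850 UMIs (median 1735) and HH27 held 2189 cells with 3414730 UMIs (median 1315). The lowest cell had 1469 UMIs at HH21, 889 at HH24 and 813 at HH27, so the libraries were also bounded at different depths. Scrublet, run through Scanpy 1.11.5, marked 2, 1 and 4 cells in HH21, HH24 and HH27. It was judged not to have worked, since these are under 0.2% of each library, and doublets were kept; removal of the 5% of cells with the highest scores per library was added as an alternative. For shares of cells carrying a gene set, and for genes per cell, each cell was also thinned to 882 UMIs, which left out 214 HH27 cells and none at the other stages.

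With 1 library per stage there was no test between stages, and no p-value is given. Shares of cells carry exact Clopper-Pearson 95% intervals, and sums of counts and their ratios carry exact Poisson 95% intervals. All intervals cover counting error only, and a count of 0 is given with the limit that 3 counts allow. Counts were summed over the cells of a class, scaled by their total to CPM and compared as log2 ratios with a pseudocount of 5 CPM. A gene was tested where it reached 20 CPM in 1 of the 2 libraries and was called higher or lower at 2-fold or more. The number of such genes that counting error alone would give was the mean over 20 pairs of libraries drawn from 1 shared profile. The median log2 ratio of the mitochondrial list was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. On simulated counts for HH27 against HH21 in mesenchyme (16828 genes, 4989 tested), the size rule recovered 100 of 100 genes changed 4-fold and 99 of 100 changed 3-fold, and took 0 of 4790 unchanged genes. Mesenchyme was the sum of the populations named as mesenchyme, connective tissue or cartilage. Cell cycle, Skin, Muscle and Vessels stayed outside it.

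The cell and depth values, shares, stage comparisons and mitochondrial list, with their thresholds, were set before the data were examined. The other parts were chosen after seeing the data, with limits set from the observed distributions. These are the correlation of population profiles, the gene sets of populations, the group of cells under 2% mitochondrial UMIs, and the split of cells by 11 genes at a limit of 0.25% of UMIs. Population profiles were log2(CPM + 5) over 4910 genes outside the mitochondrial genome, centred within each library on the mean of its populations, and compared by Pearson correlation across genes, which are not independent replicates. In 27 simulated pairs of populations (4785 genes, 100 genes changed 4-fold per population), the correct partner ranked highest in 27, and with no genes changed the largest correlation was 0.0528. A population's gene set held the 15 genes with the largest ratio over the highest other population of its library, among genes of at least 100 CPM. In a simulated HH24 Vessels population with 15 genes raised 20-fold, 15 were recovered among 16828 genes. A cell with at least 3 UMIs of a set is called a carrier.

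Alternatives covered edgeR 4.0.16 TMM factors and DESeq2 1.42.0 size factors (R 4.3.3), the pseudocount, the CPM minimum, averaging or thinning of cells, a minimum of 2000 UMIs, and subsets of cells. Other computation used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.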

Results

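The series followed the cells of the chicken limb through 3 stages of outgrowth and early tissue formation, HH21, HH24 and HH27. Transcripts were counted as UMIs in 2990, 5352 and 2189 cells, and the authors' annotation divided these into 9, 11 and 9 populations. A median cell held 2365 UMIs and 978.5 genes at HH21, 1735 UMIs and 776 genes at HH24, and 1315 UMIs and 637 genes at HH27. After every cell was thinned to 882 UMIs the medians were 486, 483 and 478 genes. There was 1 library per stage, so no difference between stages below has a replicate check.

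The first comparison asked how the make-up of the limb differed between stages. Mesenchymal populations made up 79.4% of HH21 cells (95% exact interval 77.9 to 80.8), 78.3% at HH24 (77.2 to 79.4) and 77.3% at HH27 (75.5 to 79.1). Within them, the distal mesenchyme was 23.2% of cells at HH21 (21.7 to 24.8), 16.9% at HH24 (15.9 to 17.9) and 15.1% at HH27 (13.6 to 16.7). Cells annotated as Muscle were 1.54% (1.13 to 2.05), 1.98% (1.62 to 2.39) and 5.03% (4.15 to 6.03). At HH21, 16 of these 46 cells carried vessel genes, and the share without them was 1.003%. Chondrocytes, the cartilage cells of the future skeleton, were 8.56% at HH21 (7.58 to 9.62), 17% at HH24 (16 to 18) and 5.85% at HH27 (4.90 to 6.91). The HH24 value pools the 451 cells named Chondrocytes and the 457 named Chondrocytes?, and leaves out the 466 cells named Early ch. (PFR?).

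The populations called nsCT were 17.1% at HH21 (15.8 to 18.5), 15.9% at HH24 (14.9 to 16.9) and 15.9% at HH27 (14.3 to 17.5). Skin was 3.44% (2.82 to 4.16), 2.5% (2.10 to 2.96) and 4.25% (3.44 to 5.18). Cell cycle populations held 15.6% of cells at HH21 (14.3 to 17) and 15.8% at HH24 (14.8 to 16.8), and no HH27 population carried that name. Vessels was named in 73 HH24 cells, 1.36% (1.07 to 1.71), and in 293 HH27 cells, 13.4% (12 to 14.9), and no HH21 population carried that name. Shares depended on depth at HH24 and HH27, and at HH21 for Chondrocytes and Skin only. Among cells with at least 2000 UMIs, distal mesenchyme was 23.8%, 21.6% and 19.96% of HH21, HH24 and HH27, a smaller difference than over all cells. Chondrocytes were 7.57%, 11.4% and 4.26% of these cells. For HH27, nsCT was 8.30% and Skin 10.8%, and Skin was 4.26% of HH21 and 3.94% of HH24.

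**Figure D1:**
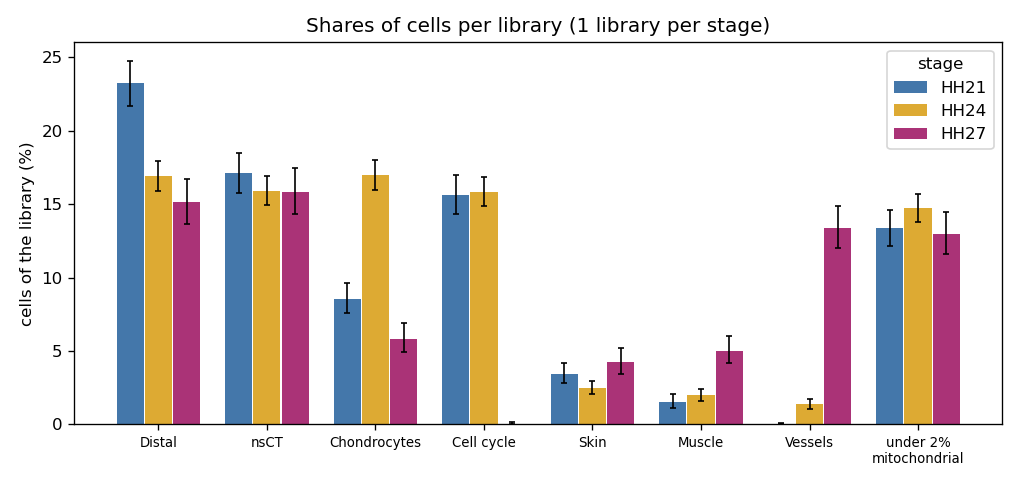
Bars give the percentage of each library's cells in a named class, and error bars the exact 95% binomial interval, for HH21 (blue), HH24 (yellow) and HH27 (purple), 1 library each. The last class is the cells with under 2% mitochondrial UMIs, which overlaps the others. Muscle reached 5.03% and Vessels 13.4% at HH27.

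Profiles of the populations were then matched between libraries, to see whether the same name covered the same expression. From HH21 to HH24 the distal mesenchyme (Pearson r = 0.78 across 4910 genes), nsCT (0.74), Dor-Ven Mes. (0.69), Chondrocytes (0.63), Skin (0.83) and Muscle (0.30) each had the population of the same name as their highest match. From HH24 to HH27 this held for Skin (0.76), Muscle (0.48) and distal mesenchyme (0.53, with 0.52 for Interdigits?). It failed for the cartilage and connective tissue names: HH27 Chondrocytes matched HH24 Early ch. (PFR?) at 0.42 and HH24 Chondrocytes at 0.22. HH27 nsCT matched HH24 Chondrocytes? at 0.50 and HH24 nsCT at 0.28, while HH24 nsCT had its highest HH27 match in the population named Mesenchyme (0.48). HH27 Vessels matched HH24 Cell cycle at 0.76, Skin at 0.56 and Vessels at 0.49, although the HH24 Vessels profile itself had HH27 Vessels as its highest match. With both HH24 profiles thinned to 49519 UMIs, and HH27 Vessels left whole, the values were 0.42 for Cell cycle and 0.40 for Vessels. HH27 Vessels cells were also split at 2% mitochondrial UMIs and matched to HH24 cells on the same side of that limit. The 127 with at least 2% matched Cell cycle at 0.25 and Vessels at 0.10 before thinning, and at 0.11 and 0.10 after it. The remaining 166 cells matched at 0.81 and 0.59 before thinning, and at 0.56 and 0.54 after it. With profiles centred on the mesenchymal populations alone, the best matches named here for distal mesenchyme, nsCT and HH27 Chondrocytes were the same populations, at lower r (0.31 for HH27 Chondrocytes with Early ch.).

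These correlations shrink with counts. With an equal number of UMIs per population, r between HH21 and HH24 was 0.36 for distal mesenchyme and 0.31 for Chondrocytes. The HH27 Chondrocytes profile, from 128 cells, had a split-half r of 0.17, or only 0.29 when adjusted to the full number of cells. For the 46 cells of HH21 Muscle (Mes.?) these values were 0.14 and 0.25, so the Muscle match of 0.30 rests on a noisy profile. The Skin correlations were 0.17 (HH21 with HH24) and 0.11 (HH24 with HH27) without cells under 2% mitochondrial UMIs, which made up at least 91.4% of Skin in every library. This removed 96 of 103, 123 of 134 and 85 of 93 Skin cells at the successive stages. So few cells remained that counting noise alone may lower r this far.

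**Figure D2:**
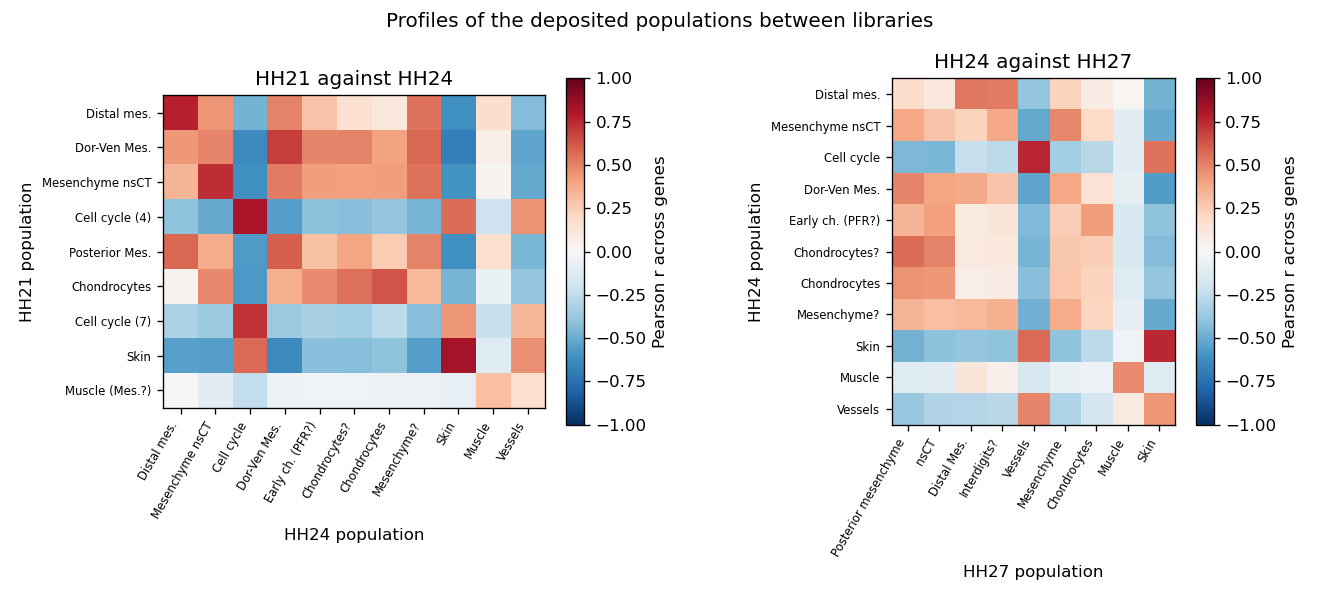
Each square is the Pearson r across 4910 genes between a population of the earlier library (vertical axis) and of the later one (horizontal axis), after centring within each library; red is positive and blue negative. Same-name squares reach 0.83 for Skin from HH21 to HH24, and the column of HH27 Vessels is darkest at HH24 Cell cycle (0.76).

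Stage differences within mesenchyme were the main comparison, because sums over all cells also move with the mix of cell types. At HH27, 348 of 5526 genes were at least 2-fold higher than at HH21 and 113 were at least 2-fold lower, where counting error alone gave 0 and 0. These counts were 166 and 60 with a pseudocount of 20 CPM, and 190 and 75 with a minimum of 50 CPM. Most of the difference lay in the later step: HH24 against HH21 had 71 higher and 4 lower of 5068 genes, and HH27 against HH24 had 210 higher and 98 lower of 5457. Run and stage differ together for HH27, so the later step cannot be assigned to stage alone. Of the genes with the largest log2 ratios, ENSGALG00000027234 stood at 1.10 CPM at HH21 (7 UMIs), 13.5 at HH24 and 108 at HH27 (274 UMIs), a log2 ratio of 4.21 and a 97.5-fold ratio (46.7 to 245). In the distal mesenchyme it went from 2.60 to 305 CPM. ENSGALG00000046616 stood at 7.73, 12 and 216 CPM, a 28.0-fold ratio (20.9 to 38.3, log2 4.12). In Chondrocytes it stood at 1.54 CPM at HH21, near the floor in a class of 649853 UMIs, and at 2380 CPM at HH27. With a pseudocount of 20 CPM their order turned, at log2 ratios of 2.60 and 3.09, and outside cartilage and connective tissue the log2 ratio of the latter was 2.19. Both were chosen after their values were seen.

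The balance of higher and lower genes depended on scaling. Of the genes past 2-fold, 75.5% were higher for HH27 against HH21, which was 60.1% with TMM factors (255 higher, 169 lower) and 57.5% with DESeq2 size factors (249 and 184). For HH27 against HH24, 68.2% were higher, against 50.9% (141 and 136) and 52.5% (145 and 131). For HH27 against HH21, these factors shifted the log2 scale by -0.13 and -0.15, before the pseudocount.

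The same comparison over all cells gave 67 genes higher and 4 lower at HH24 against HH21 (4936 tested), 169 and 92 at HH27 against HH24 (5261 tested), and 282 and 99 at HH27 against HH21 (5299 tested). The last split, 74.0% higher, was 62.3% with DESeq2 size factors (238 higher, 144 lower). By class, HH27 against HH21, the distal mesenchyme had 392 genes higher and 202 lower, with 12.2 and 22.2 from counting error alone. For nsCT the counts were 677 and 405 (29.8 and 47.6 by chance), and for Chondrocytes 946 and 575 (254 and 314 by chance). HH21 distal mesenchyme matched HH27 Interdigits? best (r = 0.51, with 0.49 for HH27 distal mesenchyme), HH21 Chondrocytes matched HH27 nsCT best (0.45) and HH21 nsCT matched HH27 Mesenchyme best (0.47), so these counts compare populations of the same name and not necessarily the same cells. Over its own tested genes Skin went the other way, with 258 genes higher and 764 lower (208 and 178 by chance), around a median log2 ratio of -0.40. Centred on that median, Skin had 507 higher and 368 lower, so its direction depended on the centring. Over the 3283 genes tested in all 4 classes, nsCT (172 higher, 270 lower) and Chondrocytes (227 and 303) also leaned lower. Distal mesenchyme had 122 and 113 there, and Skin 188 and 559. Counting error was not drawn for these shared genes, and over own tested genes it leaned lower in distal mesenchyme, nsCT and Chondrocytes. Muscle could be compared between HH24 and HH27 only, since HH21 held 46 such cells: 804 genes were higher and 610 lower, with 399 and 501 by chance.

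The summed UMIs of the 13 mitochondrial genes were a larger share of mesenchymal UMIs at later stages. That share was 5.57% at HH21, 6.20% at HH24 and 7.26% at HH27, a 1.30-fold ratio between the last and the first (1.30 to 1.31). The median log2 ratio of the list was 0.44 for HH27 against HH21, with 3 of 13 genes at least 2-fold higher and 0 lower, at the 99.9th percentile of 10000 matched random lists. For the steps it was 0.11 (0 of 12 genes past 2-fold, 99.4th percentile) and 0.32 (2 of 13 past 2-fold, 99.6th percentile). Scaling lowered the second step to 0.19 with TMM factors, and HH27 against HH21 to 0.30 with TMM factors and 0.28 with DESeq2 size factors, and in cells with at least 2000 UMIs it was 0.19 for that step and 0.26 for HH27 against HH21.

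Mitochondrial content per cell fell into separate groups. Cells with under 2% mitochondrial UMIs were 13.3% of HH21 (12.1 to 14.6), 14.7% of HH24 (13.8 to 15.7) and 13% of HH27 (11.6 to 14.5). They were 93.2%, 91.8% and 91.4% of Skin at the successive stages. Such cells made up 55.5% and 64.1% of the Cell cycle populations at HH21 and 61.5% at HH24, and 60.3% of Vessels at HH24 and 56.7% at HH27. Outside Skin, 176 genes were at least 2-fold higher in these cells than in all others in every library, where independent lists would share 3.02, and 1144 were lower in every library (172 from independent lists), of 4816 genes tested in all 3. Their log2 ratios correlated across genes between libraries at 0.94 (HH21 with HH24) and 0.85 (HH21 with HH27). Of the low cells outside Skin, 270 of 303 at HH21, 564 of 664 at HH24 and 166 of 199 at HH27 were in Cell cycle or Vessels. The cells they were compared with were mostly mesenchyme (2347 of 2591, 4102 of 4565 and 1671 of 1905). The overlap and correlations can therefore reflect the same populations set against mesenchyme in each library. Among HH27 cells with at least 2000 UMIs, cells under 2% mitochondrial UMIs were 21.5%.

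**Figure D3:**
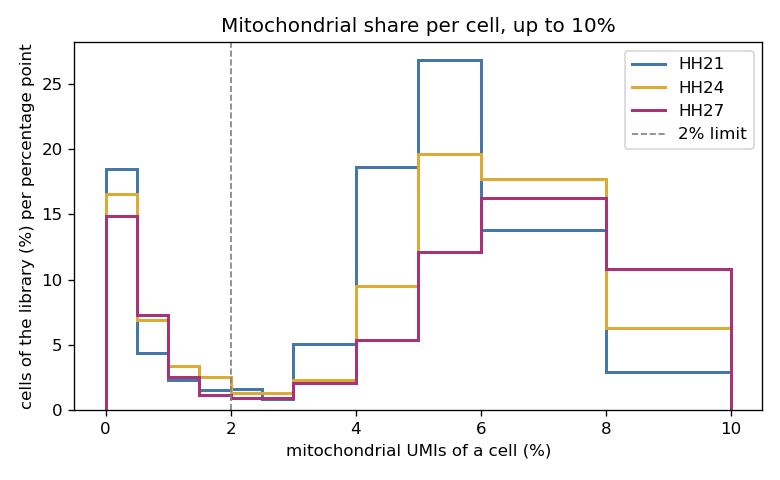
The horizontal axis is the mitochondrial percentage of a cell's UMIs, up to 10%, and the vertical axis the percentage of a library's cells per percentage point. Each line is 1 library, the dashed line marks 2%, and cells on its left are 13.3%, 14.7% and 13% of HH21, HH24 and HH27.

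A block of 11 genes was present at HH21 and HH24 and had 0 UMIs in the whole HH27 library. The 2 genes with the lowest log2 ratios in mesenchyme belong to it: ENSGALG00000035998 stood at 6655 CPM at HH21, 5061 at HH24 and 0 at HH27, at least 5645-fold lower than at HH21 against a floor of 3 UMIs. ENSGALG00000048286 stood at 521, 445 and 0 CPM, at least 442-fold lower. Together the 11 genes took 7381 CPM of the HH21 library and 5794 CPM of HH24. By the same rule, at least 5 CPM in both other libraries and 0 in the remaining one, 0 genes were missing from HH21 alone and 0 from HH24 alone.

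At HH21 and HH24 the summed share of these genes was high in some cells and low in others. The split rests mainly on ENSGALG00000035998. In mesenchyme alone it held 42185 of the library's 60853 block UMIs at HH21 and 42103 of 62809 at HH24. Whether the other genes follow it cell by cell was not examined. Cells with under 0.25% of UMIs in these genes were 1151 of 2990 at HH21, 38.5% (36.7 to 40.3), and 2360 of 5352 at HH24, 44.1% (42.8 to 45.4). Only 37 and 236 cells lay near the limit, between 0.15% and 0.4%. In the cells without the block the sum of its genes stood at 4% and 5.95% of its library level. Every population of both libraries held cells of both kinds, from 24.4% without the block in the distal mesenchyme (21.2 to 27.7) to 58.1% in Dor-Ven Mes. (53.9 to 62.1) at HH21, and from 35.6% in Vessels to 58.3% in Mesenchyme? at HH24. With only cells without the block, HH27 against HH21 in mesenchyme gave 359 genes higher and 118 lower, of which 315 and 97 were also in the lists from all cells.

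**Figure D4:**
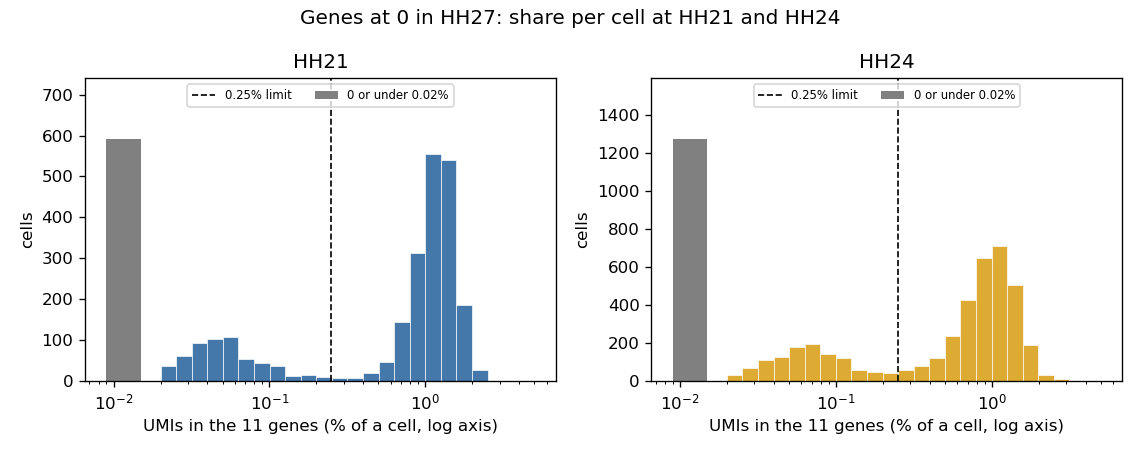
Bars count cells by the percentage of their UMIs in the 11 genes that had 0 UMIs in HH27, on a log axis, for HH21 (left) and HH24 (right). The grey bar holds cells at 0 or under 0.02%, and the dashed line is the 0.25% limit; 38.5% of HH21 and 44.1% of HH24 cells lie on its left.

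Vessel and muscle cells were traced with gene sets learned in 1 library and read in the others. The 15 genes of the HH24 Vessels set, each at least 20.8-fold above any other HH24 population, were carried by 55 of 73 HH24 Vessels cells, 75.3% (63.9 to 84.7). The set was chosen from these same cells, which favours that share. Of the HH27 Vessels cells, 5 of 293 carried the set, 1.71% (0.556 to 3.94). After thinning to 882 UMIs the shares were 58.9% and 1.55%. The set stood at 4179 CPM in HH24 Vessels and 153 CPM in HH27 Vessels, beside 13.6, 21 and 18.1 CPM in the mesenchyme of the 3 libraries. At HH21, where no population was named Vessels, 16 of the 46 cells of Muscle (Mes.?) carried it, 34.8% (21.4 to 50.2), and 17 of all 2990 cells, 0.569% (0.332 to 0.909).

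That HH21 population split by cell: 27 cells carried the HH24 muscle set, 16 the vessel set, 1 both and 4 neither. The HH24 muscle set separates its population weakly, its least specific gene being 1.83-fold above the next population, and 10.4% of HH21 mesenchymal cells carried it, against 0 of 2374 for the vessel set. With the genes of both sets left out, the 16 vessel carriers matched HH24 Vessels best (r = 0.39 across genes) and the other 30 cells matched HH24 Muscle best (0.36). The set learned in HH27 Muscle held 15 genes at least 11.3-fold above any other HH27 population. It stood at 8022 CPM in HH27 Muscle, 1232 CPM in HH24 Muscle (1096 to 1380) and 323 CPM in HH21 Muscle (233 to 437). Its genes were chosen for their level in HH27 Muscle, which favours lower values in the other libraries. The HH24 muscle set stood at 3613, 3055 and 1715 CPM in the same populations. In mesenchyme the HH27 set stood at 45.9, 57.9 and 52.3 CPM at HH21, HH24 and HH27. The HH21 level of the HH27 set was not specific to muscle, since that set also stood at 329 CPM in HH24 Vessels (244 to 435). It stood at 123 CPM in HH21 Chondrocytes.

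**Figure D5:**
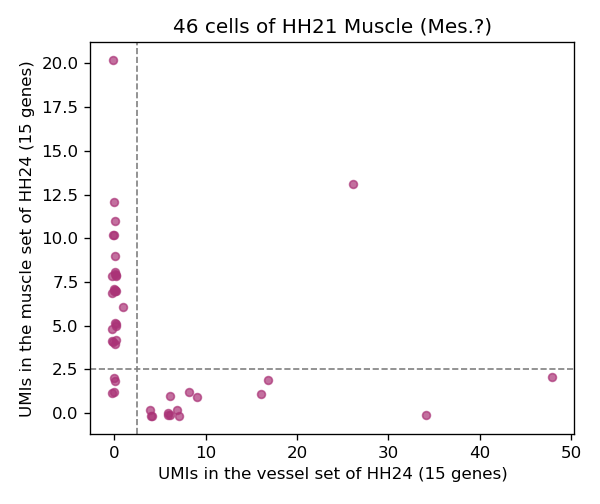
Each point is 1 of the 46 cells of HH21 Muscle (Mes.?), with its UMIs in the HH24 vessel set (horizontal) and in the HH24 muscle set (vertical), shifted slightly at random so that points do not hide each other. Dashed lines mark the limit of 3 UMIs; 1 cell lies past both.

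The order of the stages by deposited G2M score turned with the depth of the cells used, and the order by S score did not. Over all mesenchymal cells the median G2M score was 0.363 at HH21, 0.499 at HH24 and 0.645 at HH27. Among cells of 1500 to 2500 UMIs the order was opposite, 0.441, 0.390 and 0.341. The median S score was 0.768, 0.832 and 0.972 over all cells and 0.817, 0.838 and 0.958 in that UMI window. In the Cell cycle and Vessels populations, cells under 2% mitochondrial UMIs had median G2M scores of 0.031, 0.040 and 0.075, against 0.576, 0.789 and 0.747 in the remaining cells.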

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

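The patterns here were found in the data and no test of them was planned; the centring on the median gene was chosen only after the result was seen. Over each class's own tested genes, Skin had a balance opposite to the 3 mesenchymal classes in both comparisons that involve HH27. Against HH24, 802 Skin genes were at least 2-fold lower and 217 higher (189 and 205 from counting error alone, so the higher count is about what chance gives). Against HH21, 764 were lower and 258 higher. Distal mesenchyme, nsCT and Chondrocytes each had more genes higher than lower. This depended on the genes tested. Over the 3358 genes tested in all 4 classes, every class had more lower than higher for HH27 against HH24. Higher and lower counts were 107 and 113 (distal mesenchyme), 127 and 267 (nsCT), 189 and 257 (Chondrocytes) and 146 and 613 (Skin). Against HH21 (3283 genes) they were 122 and 113, 172 and 270, 227 and 303, and 188 and 559. Counting error was not drawn for these shared genes. Over each class's own genes, HH27 against HH24, it leaned lower itself: 11 and 23.5 (distal mesenchyme), 23.25 and 40.4 (nsCT), 181 and 246 (Chondrocytes). The lower balance of distal mesenchyme and Chondrocytes over shared genes may thus be counting error. The difference between the classes was not tested, since each stage has 1 library. Relative to the median gene, which lay at -0.40, Skin had 507 genes higher and 368 lower for HH27 against HH21, so the balance turned with the centring. The 50 most abundant genes took 33.4% of Skin UMIs at HH21, 33.1% at HH24 and 41.5% at HH27.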

How the results depend on the processing

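All alternatives that leave out cells by mitochondrial content, by the 11-gene block, by the highest doublet scores or by vessel genes, that add Cell cycle cells, that centre Skin on its median gene, that fix a UMI window for the scores, or that change correlations and gene sets were chosen after seeing the data. No paired analysis was possible because each stage has 1 library and the labels give no replicate numbers to pair. None of the log2 ratios and correlations followed through the alternatives changed sign, a check that counts and shares cannot fail. The balance of genes in Skin turned with centring, and the order of the stages by G2M score turned in a window of 1500 to 2500 UMIs. In mesenchyme, having no CPM minimum gave the same gene counts as a minimum of 5 CPM, so these are not separate checks. Of the results that answer a comparison, 298 values under alternatives stayed within their limits and 61 moved beyond them; of the others, 96 stayed and 34 moved. The cause of a move was not tested unless the alternative itself shows it.

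Rules on low expression changed the counts of genes by construction. With a pseudocount of 20 CPM, mesenchyme had 30 higher and 2 lower genes for HH24 against HH21, 87 and 54 for HH27 against HH24, and 166 and 60 for HH27 against HH21. With a minimum of 50 CPM the higher counts were 41, 116 and 190, and the lower count for HH27 against HH21 was 75. With a minimum of 5 CPM, all cells had 254 higher genes for HH27 against HH24 and 429 for HH27 against HH21. DESeq2 size factors raised the lower count for HH27 against HH21 in mesenchyme to 184. The small count of 4 lower genes at HH24 against HH21 became 7 in mesenchyme outside cartilage and connective tissue and 12 with only cells lacking the 11-gene block, and 15 over all cells with that restriction. Centred on the median gene, Skin had 507 genes higher and 368 lower. The mitochondrial median was 0.19 for HH27 against HH24 with TMM factors, 0.19 and 0.26 for HH27 against HH24 and HH21 in cells with at least 2000 UMIs, and 0.084 for HH24 against HH21 over all cells with DESeq2 size factors.

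Among cells with at least 2000 UMIs, Chondrocytes were 7.57%, 11.4% and 4.26% of HH21, HH24 and HH27, and Skin was 4.26%, 3.94% and 10.8%. Distal mesenchyme was 21.6% of HH24 and 19.96% of HH27, Vessels 1.02% of HH24, and at HH27 nsCT was 8.30%, mesenchyme 70.4% and cells under 2% mitochondrial UMIs 21.5%. Without the latter cells, mesenchyme was 90.6%, 89.9% and 87.7%, distal mesenchyme 26.5%, 19.8% and 17.1%, nsCT 19.5%, 18.3% and 17.9%, and Skin 0.270%, 0.241% and 0.420% at the successive stages. Cell cycle was then 7.60% of HH21 and 7.14% of HH24, Chondrocytes 19.0% of HH24, and Vessels 0.635% of HH24 and 6.67% of HH27. Without carriers of the vessel set, Muscle was 1.003% of HH21. A limit of 1% gave 11.4%, 11.7% and 11.1% of low mitochondrial cells, and a limit of 3% gave 16% at HH24. In the UMI window the S medians of HH21 and HH27 were 0.817 and 0.958, and the G2M medians were 0.441, 0.390 and 0.341.

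Several alternatives set at the outset need gene names and were not run: totals without haemoglobin and ribosomal genes, removal of erythroid or haemoglobin-rich cells, limb identity genes, gene lists other than the mitochondrial one, cell cycle lists and clusterings named from markers. For the scaling alternative, totals without mitochondrial genes alone were used. Calls in small populations, such as the 93 HH27 Skin cells, lie closer to counting error than those in mesenchyme.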

Other observations

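The comparison across classes, the gene sets and each of the 8 tests of explanations reported here were chosen only after the results were seen, and the vessel score was revised once after its first output. A group of 23 genes was at least 2-fold higher at HH24 than at HH21 in distal mesenchyme, nsCT, Chondrocytes and Skin alike. Independent lists would share 0.000471, but the 4 classes come from the same libraries, so their lists are not independent. Their summed level in distal mesenchyme was 2527 CPM at HH21, 8632 at HH24 and 4462 at HH27, and in Skin 1321, 5617 and 2445 CPM. The ratio of HH24 to HH21 was 3.24 in Muscle and 4.25 in Skin. The genes were chosen for their rise at HH24 in the 4 classes, Skin among them, which favours these ratios and a lower level at HH27. Muscle was not used in that choice, but it comes from the same libraries. At HH27 only 1 of the 23 was at least 2-fold above HH21 in all 4 classes, although their summed level stayed above that of HH21 in each. For HH27 against HH21, 28 genes were higher in all 4 classes and 23 were lower, 4 of the latter in the block of 11. With 1 library per stage, a change shared by all classes cannot be separated from a property of the library.

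The block of 11 genes at 0 in HH27 is too large for chance or depth, since 19786 UMIs were due in HH27 at the HH24 rate. The split of cells by the block, used below, rests mainly on ENSGALG00000035998. If the genes had merely been left out when HH27 was counted, other genes would be unaffected, and this was examined with 42 genes at least 0.5 log2 higher in HH21 mesenchymal cells without the block (3 were lower, of 2120). In HH24 cells without the block 42 of the 42 were higher too, with a median of 0.78 (1.71-fold), and in HH27 they lay 0.58 log2 above HH24 cells with the block, relative to all genes, but only -0.11 from HH24 cells without it. HH27 thus resembled the cells without the block, which is consistent with embryos with and without these genes in the HH21 and HH24 libraries and only embryos without them at HH27. The number and sex of the embryos per library are not given in the sources used here, but with only cells without the block 315 of the 348 higher and 97 of the 113 lower genes of HH27 against HH21 mesenchyme remained. Genes of the female-specific W chromosome, with a higher dose of Z-linked genes in males, are a candidate explanation, which remains a hypothesis because nothing used here places these identifiers on chromosomes.

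Cells under 2% mitochondrial UMIs do not look like shallow cells: their median non-mitochondrial UMIs were at least 1.05 times those of other cells in every library, and outside Skin they were 2371 against 2207, 1618 against 1619 and 1399 against 1189. Outside Skin their median genes per cell were lower, at 932 against 982, 714 against 780 and 593 against 639. Damage to cells was not examined beyond depth and stays open. In the low cells outside Skin, the skin gene set reached at most 2.94% of its level in Skin. The set was chosen in HH24 against the other populations, which favours a low value there. At HH21 it stood at 87.3 CPM against 6197 in Skin, and at HH27 at 136 against 4625. Much RNA of these genes from Skin is thus unlikely there. Skin-like cells that lack these genes are not covered, and the annotation had already set Skin apart. Whether the cells under 2% mitochondrial UMIs came from particular embryos stays open. Of these cells 32.1% at HH21 and 40.9% at HH24 lacked the block of 11 genes, against 39.5% and 44.6% of other cells. That the block marks embryos is untested. Outside Skin most were Cell cycle or Vessels cells compared with mesenchyme, so their shared profile across libraries cannot separate mitochondrial content from population. A cell state or type that these names divide from the rest only in part stays open. So does an effect of tissue handling that recurs in each library.

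The HH27 cells named Vessels mostly lacked the vessel set. The lower depth of that library is unlikely to account for it alone, since HH24 Vessels cells thinned to 882 UMIs kept the set in 58.9%. The set was chosen from those HH24 cells, which favours that share. A per-cell score without the set genes placed 33 of 37 HH24 Vessels cells kept aside on the vessel side (89.2%, 74.6 to 97.0) and 2 of 423 HH24 Cell cycle cells. It placed there 12 of 293 HH27 Vessels cells (4.10%, 2.13 to 7.04), among them 5 of the 5 carriers of the set, but also 26 of 93 HH27 Skin cells, so the score is not specific to vessels. These values are consistent with a name that covers few vessel cells, while a change of vessel genes between the stages stays open and was not tested. What the other cells are also stays open. With only the HH24 profiles thinned to 49519 UMIs, the whole population was hardly closer to HH24 Cell cycle (0.42) than to HH24 Vessels (0.40). Against HH24 cells on the same side of the limit, its 166 cells under 2% mitochondrial UMIs stood at 0.56 and 0.54. The remaining 127 matched neither well (0.11 and 0.10). Before thinning, Cell cycle was the closer each time (0.76, 0.81 and 0.25, against 0.49, 0.59 and 0.10 for Vessels).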
